A study of Mus musculus with 308 samples.

How the data were processed

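Gene expression was measured in 308 arrays of an Affymetrix mouse platform, HT MG-430 PM, made from 7 tissues of C57BL/6 mice. Per the labels, mice were dosed once daily for 10 days and tissue was taken 12 h after the last dose. The vehicle was 0.8% HPMC (hydroxypropyl methylcellulose). Treatments were dimethyl fumarate (DMF) at 100 or 179.2 mg/kg, the calcium, magnesium and zinc salts of monoethyl fumarate (MEF) at 79.2 mg/kg, and the combination of DMF at 100 mg/kg with MEF salts at 79.2 mg/kg. A further group is labelled Nav, and the sources used here do not explain the name. Groups were taken from the sample titles, since another label field gives the DMF group at 100 mg/kg and the combination the same text.

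The deposited table holds log2 expression values of 45141 probe sets. Per the labels, the authors used RMA, GCRMA, R 2.11.1 and limma 3.4.5. Which tool did which step, and how background was handled, is not given in the sources used here. Within a tissue all arrays share the same lowest value, which differs between tissues, and array medians are nearly equal. The tissues were therefore treated as normalized apart. Treatments were set against vehicle only within a tissue, and the interaction test alone compared these responses between tissues. Between 18.48 and 23.35% of a tissue's values sit at its lowest value, so low levels are compressed. The number of arrays per group limits the precision.

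Of the probe sets, 29449 were found in the gene name table and 28898 of these carry 1 gene symbol. A further 551 carry several symbols and 15692 were not named, and both kinds were kept out of the comparisons. The gene identifiers of 28689 single-symbol probe sets matched the RefSeq table of assembly GRCm38.p6, which was used for names only. For each of 17097 genes, the probe set with the highest mean over all arrays was used. A gene was tested in a tissue when its probe set lay above the tissue's 50th percentile in at least 5 arrays, which left between 10378 and 10847 genes per tissue. The 104 control probe sets served for quality checks.

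For each tissue, limma 3.58.1 in R 4.3.3 (data.table package, version 1.17.8) fitted 1 mean per group and a moderated variance per gene. Each treatment was set against vehicle. Direct comparisons set DMF at 179.2 mg/kg against DMF at 100 mg/kg, the combination against DMF at 100 mg/kg, MEF salts against DMF at 100 mg/kg, and DMF at 179.2 mg/kg against the combination. The departure of the combination from the sum of its parts on the log2 scale was tested too. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and the number changed at least 1.5-fold is given beside the calls. Values are log2 fold changes ± standard error from limma unless stated. Intervals are 95% confidence intervals of the fitted difference.

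A set of 45 gene lists was written from general knowledge, and each was tested with limma's fry in tissues where enough members were tested. fry asks whether a list's genes move, on balance, in 1 direction, and does not compare them with other genes. Adjustment ran over all lists and treatments of a tissue. Counts of list members adjusted over the list alone are given beside counts over all genes. A second test, camera with an estimated correlation, compares a list with other genes. Genes whose response differed among the 7 tissues were found with an F test of the tissue by treatment interaction over 7849 genes tested in every tissue. That test fits 1 variance per gene over all tissues, although the tissues were otherwise fitted apart because their spread differs. It also takes arrays of different tissues as independent, which the correlation of arrays with equal replicate numbers argues against.

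Named genes are up to 8 that rose and 8 that fell by size in each tissue and treatment, up to 4 called members of a list by smallest adjusted p, 5 each way in direct comparisons, and a fixed set of genes of the antioxidant response, metallothioneins and fumarate handling. Genes outside this rule are said to have been chosen after their values were seen. The groups, comparisons, lists, naming rule and most alternatives were fixed before the data were examined. Alternatives were no filter, a filter at the 70th percentile, renewed quantile normalization, centring of each array, a trended robust variance, array weights, the mean of a gene's probe sets, the groups compared as a pair alone, the replicate number as a block, and leaving out arrays of a small group. The alternatives that left out arrays of low correlation, or used the signal of the hybridisation controls as a covariate, were chosen after seeing the data.

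The calling step was tested on simulated data with 50 genes changed per fold. For DMF at 179.2 mg/kg in jejunum, 10847 genes, it recovered 42% of genes changed 1.25-fold, 86% at 1.5-fold and 100% at 2-fold, and 9 of 173 calls were false. For MEF salts in blood, 10378 genes, the shares were 34, 76 and 92%, and for MEF salts in spleen, 10549 genes, 52, 92 and 98%. Simulated changes in jejunum alone, over 7849 genes, were recovered by the interaction test at 46, 90 and 100%. Of 200 unchanged lists simulated for MEF salts in jejunum, 2% had fry p under 0.05. The simulations drew independent normal noise for each gene and array, without correlation between genes, array effects or a lowest signal. The interaction simulation also used 1 spread per gene for all tissues. The shares of false calls therefore need not hold for the real arrays.

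Counts of calls were compared with 100 random splits of the same arrays. Comparisons of single values between groups used 2-sided exact permutation tests. The labels do not state that replicate numbers are separate animals, so p-values measure the spread between samples.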

Results

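The data are log2 expression values from 308 arrays covering blood, brain, inguinal lymph node, jejunum, kidney, mesenteric lymph node and spleen. Mice received vehicle, DMF at 100 mg/kg (DMF100), DMF at 179.2 mg/kg (DMF179.2), MEF salts at 79.2 mg/kg (MEF79.2), DMF100 with MEF79.2 (the combination), or belonged to the group labelled Nav. Groups held between 5 and 8 arrays, and their sizes are given per tissue in the order vehicle, DMF100, DMF179.2, MEF79.2, combination, Nav. Array medians ranged from 3.362 to 3.408 in blood and from 5.697 to 5.831 in brain, the lowest and highest of the 7 tissues, each on its own normalization. DMF and MEF are related esters of fumarate, and the comparisons ask which genes each compound changes in each tissue and where the compounds differ.

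In jejunum (8, 6, 7, 7, 8 and 7 arrays), Ces1g, Cbr3 and Akr1b8 had the largest called increases under DMF100, DMF179.2 and the combination, and Ces1g, Ces1f and Akr1b8 under MEF79.2. Ces1g, a carboxylesterase that hydrolyses esters, rose by 4.53 ± 0.44 under DMF100 (adjusted p = 1.6e-09), 4.88 ± 0.41 under the combination and 5.87 ± 0.42, or 58.5-fold, under DMF179.2. Cbr3, a carbonyl reductase, rose by 3.69 ± 0.29, 4.40 ± 0.27 and 5.42 ± 0.28 from a dim vehicle level (3.89, below the filter's 4.89), and the aldo-keto reductase Akr1b8 rose by 3.56 ± 0.23, 4.24 ± 0.21 and 4.92 ± 0.22. Glutathione transferase Gstm1 rose by 2.35 ± 0.25, 2.67 ± 0.23 and 3.17 ± 0.24 in the same order, and the glucuronosyl transferase Ugt2b5 by 2.31 ± 0.29, 2.87 ± 0.27 and 3.67 ± 0.28. Nqo1, a quinone reductase used as a marker of the transcription factor NRF2, rose by 1.45 ± 0.12, 1.58 ± 0.11 and 1.94 ± 0.11. MEF79.2 raised Ces1g by 2.00 ± 0.42 (adjusted p = 0.031), Ces1f by 1.86 ± 0.25, Akr1b8 by 1.72 ± 0.22 and Nqo1 by 0.67 ± 0.11.

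Of 35 tested NRF2 target genes in jejunum, 17 rose under DMF100 (26 adjusted over the list alone), with a list mean of 0.86 ± 0.10 and fry adjusted p = 4e-11. Under DMF179.2, 29 rose and 1 fell (30 and 1 adjusted over the list alone), with a mean of 1.36 ± 0.09 and fry adjusted p = 3.5e-17. The combination raised 24 (27 adjusted over the list alone, with 1 lower), and MEF79.2 raised 4 (11 adjusted over the list alone), with fry adjusted p = 0.00695 and adjusted p = 0.0574 with an estimated correlation. Gclc and Gclm, which encode the subunits that make the glutathione precursor, rose by 0.74 ± 0.16 and 0.62 ± 0.14 under DMF179.2, and Gclc was at 0.57 ± 0.17 under DMF100 (adjusted p = 0.10). Glutathione peroxidases and synthesis genes outside that list rose at 10 of 16 under DMF179.2 (10 and 1 lower adjusted over the list alone; fry adjusted p = 2.31e-09, and 0.0661 with an estimated correlation). Targets of the xenobiotic receptors CAR and PXR rose at 10 of 11 under DMF179.2 (10 adjusted over the list alone; fry adjusted p = 5.82e-05, and 0.418 with an estimated correlation). Srxn1, an NRF2 target elsewhere, fell by 0.16 under DMF179.2, a call lost when a gene's probe sets were averaged.

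**Figure D1:**
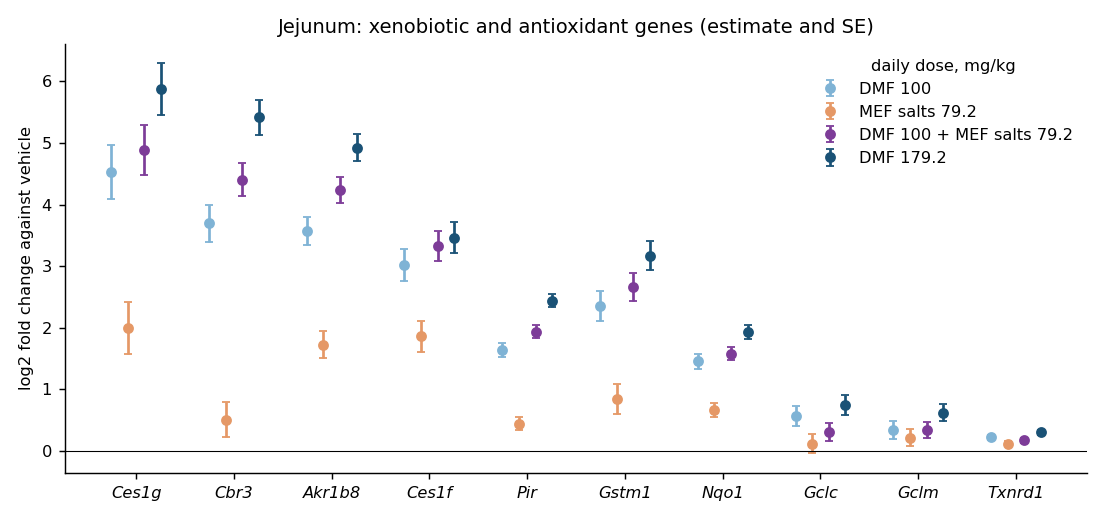
Log2 fold change against vehicle in jejunum for genes of detoxification and the antioxidant response, with standard errors, under 4 treatments. Ces1g ranges from 2.00 under MEF79.2 to 5.87 under DMF179.2.

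Among jejunal genes that fell under DMF179.2 were Fabp6, the ileal bile acid binding protein, which fell by 5.23 ± 1.64 (adjusted p = 0.016), and Fgf15, the bile acid signal from gut to liver, which fell by 3.54 ± 1.19. Saa1 fell by 3.90 ± 1.05 and Ubd, an interferon-responsive ubiquitin-like gene, by 2.74 ± 0.91. DMF100 lowered Chac1, which degrades glutathione, by 2.05 ± 0.44 and the sterol synthesis gene Hmgcs1 by 0.96 ± 0.21. Interferon-stimulated genes fell at 8 of 21 under DMF179.2 (13 adjusted over the list alone; fry adjusted p = 0.0321, and 0.567 with an estimated correlation). Cholesterol synthesis genes fell at 6 of 17 (10 adjusted over the list alone; fry adjusted p = 0.0412, and 0.574 with an estimated correlation). Under MEF79.2, Hoxc4 fell by 0.51 and Ntn1 by 0.38, and 0 smooth muscle and enteric neuron markers of 9 passed in limma over all genes (6 lower adjusted over the list alone; fry adjusted p = 0.0296, and 0.413 with an estimated correlation).

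Calls in jejunum numbered 108 under DMF100 (77 rose, 31 fell, 43 at least 1.5-fold), 2969 under DMF179.2 (1688 rose, 1281 fell, 497), 12 under MEF79.2 (9 rose, 3 fell, 7) and 416 under the combination (240 rose, 176 fell, 85). With each array centred on its median the split under DMF179.2 was 1415 that rose and 1681 that fell, and under MEF79.2 it was 14 and 1. Array weights gave 521 under DMF100 and 197 under MEF79.2. The hybridisation controls, added transcripts that no treatment should move, were lower than in vehicle by −0.14 under DMF100, −0.17 under DMF179.2, −0.08 under MEF79.2 and −0.20 under the combination (exact permutation test, adjusted p between 0.00181 and 0.00272). They were lower in Nav too, by −0.14 (exact permutation test, adjusted p = 0.00233). Every other group thus lay below vehicle, and a technical difference of the vehicle arrays cannot be told apart from treatment here. With the signal of the hybridisation controls as a covariate, a choice made after seeing the data, counts under the treatments were 69, 1128, 5 and 50. It raised the median standard error by a factor of 1.32, 1.48, 1.12 and 1.64, while the median size of the DMF179.2 calls went from 0.342 to 0.314. The calls of Fabp6, Saa1 and Srxn1 under DMF179.2, of Chac1 and Hmgcs1 under DMF100, and of Ces1g, Hoxc4 and Ntn1 under MEF79.2 ended with it, whereas Cbr3, Akr1b8, Gstm1, Ugt2b5 and Nqo1 kept theirs under DMF100, DMF179.2 and the combination. Fabp6 moved from −5.23 ± 1.64 to −7.17 ± 2.42 (adjusted p = 0.0504), Saa1 to −3.98 ± 1.58, Chac1 to −2.03 ± 0.59, Hmgcs1 to −1.08 ± 0.28 and Ces1g to 1.96 ± 0.48, so these calls ended mainly by a wider spread. Srxn1 moved to −0.07 ± 0.08, Hoxc4 to −0.53 ± 0.12 and Ntn1 to −0.34 ± 0.09. The MEF79.2 calls of Ces1g, Hoxc4 and Ntn1 also ended without the filter, and all of these and Nqo1 ended when the groups were compared alone.

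In kidney (7, 8, 8, 7, 8 and 8 arrays), Cbr3 rose by 2.23 ± 0.13 under DMF100 (adjusted p = 1.2e-16), 2.63 ± 0.13 under DMF179.2, 2.25 ± 0.14 under MEF79.2 and 2.69 ± 0.13 under the combination. Ugt2b5 rose by 1.66 ± 0.27, 2.13 ± 0.27, 2.04 ± 0.28 and 2.42 ± 0.27, and Gstm3 by 1.18 ± 0.18, 1.82 ± 0.18, 1.47 ± 0.19 and 1.98 ± 0.18. Nqo1 rose by 0.82 ± 0.08, 1.06 ± 0.08, 0.89 ± 0.09 and 0.97 ± 0.08, and heme oxygenase Hmox1 by 0.49 ± 0.07, 0.80 ± 0.07, 0.48 ± 0.08 and 0.85 ± 0.07. Aldh3a1, an aldehyde dehydrogenase, rose by 1.78 ± 0.39 under DMF100, 2.53 ± 0.39 under DMF179.2 and 2.75 ± 0.39 under the combination, and stood at 0.40 under MEF79.2. Vehicle levels of Aldh3a1, Ugt2b5 and Gstm3 (4.17, 3.47 and 3.79) lay below the filter's level of 5.1, so these changes start from dim signal. The 1 other probe set of Gstm3 did not rise under DMF100. Slc10a2, the bile acid transporter of the proximal tubule, fell by 0.92 ± 0.17, 1.79 ± 0.17, 1.60 ± 0.18 and 1.84 ± 0.17, and the histamine-forming enzyme Hdc fell by 1.27 ± 0.32, 1.80 ± 0.32, 1.49 ± 0.33 and 1.14 ± 0.32. Metallothionein Mt1 rose by 0.29 ± 0.07 under DMF179.2 and 0.33 ± 0.07 under the combination, the latter call ending when probe sets were averaged.

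Of 37 tested NRF2 targets in kidney, 25 rose under DMF100 (27 adjusted over the list alone, mean 0.44 ± 0.03), 20 under MEF79.2 (24 adjusted over the list alone, mean 0.39 ± 0.04) and 27 under the combination (28 adjusted over the list alone, mean 0.60 ± 0.03). Under DMF179.2, 29 rose and 1 fell (29 adjusted over the list alone rose), with a mean of 0.58 ± 0.03 and fry adjusted p = 3.97e-19, and the list passed with an estimated correlation under all 4 treatments. Interferon-stimulated genes, among them Rtp4, Usp18 and Oasl2, fell at 5, 9, 8 and 11 of 16 under DMF100, DMF179.2, MEF79.2 and the combination (8, 12, 9 and 11 adjusted over the list alone). Their fry adjusted p ran from 1.28e-05 to 0.000115, and with an estimated correlation from 0.0749 to 0.122. Cell cycle genes, among them Tyms, E2f1 and Pcna, rose at 5 of 15 under DMF179.2 and 8 of 15 under the combination (5 and 10 adjusted over the list alone; fry adjusted p = 0.00393 and 1.42e-05; adjusted p = 0.586 and 0.331 with an estimated correlation). Under DMF179.2, kidney injury genes rose at 5 and fell at 1 of 11 (5 and 1 adjusted over the list alone; fry adjusted p = 0.00256, and 0.586 with an estimated correlation), the fibrinogen genes Fga, Fgb and Fgg by 0.66, 0.93 and 0.92. Proximal tubule markers fell at 5 and rose at 1 of 13 (6 and 4 adjusted over the list alone; fry adjusted p = 0.0225, and 0.56 with an estimated correlation). Calls numbered 866 under DMF100 (483 rose, 383 fell, 59 at least 1.5-fold), 1786 under DMF179.2 (1134, 652, 124), 1520 under MEF79.2 (937, 583, 52) and 3245 under the combination (1891, 1354, 127). Array weights gave 2684 under MEF79.2.

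In the mesenteric lymph node (8, 8, 8, 7, 6 and 7 arrays), Nqo1 rose by 1.22 ± 0.13 under DMF100, 1.98 ± 0.13 under DMF179.2 (adjusted p = 8.2e-15), 0.44 ± 0.13 under MEF79.2 and 1.57 ± 0.14 under the combination. The MEF79.2 call ended without the filter, with array weights, with averaged probe sets, with the control covariate and with the groups compared alone. The peptide transporter Slc15a2 rose by 2.54 ± 0.70 under DMF100 and 2.41 ± 0.76 under the combination, calls that ended without the filter and with the groups compared alone, and 1 of its 2 other probe sets moved the same way. DMF100 raised heat shock genes at 6 of 12 (9 adjusted over the list alone; fry adjusted p = 4.3e-06, and 0.0226 with an estimated correlation), with Hspa1b up by 1.40 ± 0.25. DMF179.2 and the combination raised Cd209f, a lectin of macrophages and dendritic cells, by 1.27 ± 0.23 and 1.14 ± 0.24, and lowered the lymphocyte factor Ikzf3 by 0.79 ± 0.19 and 0.68 ± 0.21, the latter ending when probe sets were averaged. Under MEF79.2, Clca3a1 fell by 0.94 ± 0.18 and Nudt12 by 0.99 ± 0.30, the call of Nudt12 ending under 6 alternatives.

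Of 31 NRF2 targets in the mesenteric node, 4 rose under DMF100 (8 adjusted over the list alone; fry adjusted p = 0.0022, and 0.505 with an estimated correlation). There were 23 under DMF179.2 (27 adjusted over the list alone, mean 0.49 ± 0.07, fry adjusted p = 5.34e-09) and 19 under the combination (21 adjusted over the list alone; fry adjusted p = 6.34e-07, and 0.136 with an estimated correlation). Under MEF79.2, Nqo1 was the 1 called member (5 adjusted over the list alone), and the list's fry adjusted p was 0.517. B cell markers, among them Ralgps2, Spib, Cr2 and Cd22, fell at 5 of 15 under DMF179.2 (14 adjusted over the list alone; mean −0.29 ± 0.09, fry adjusted p = 0.0157, and 0.527 with an estimated correlation). Monocyte and macrophage markers rose at 4 of 17 (4 adjusted over the list alone; fry adjusted p = 0.0203, and 0.83 with an estimated correlation). Lipogenesis genes, whose products make fatty acids, rose at 4 of 9 (8 adjusted over the list alone; fry adjusted p = 0.029, and 0.83 with an estimated correlation), Elovl6 by 1.22 ± 0.38. Calls numbered 197 under DMF100 (144 rose, 53 fell, 24 at least 1.5-fold), 841 under DMF179.2 (656, 185, 107), 507 under MEF79.2 (159, 348, 5) and 1358 under the combination (977, 381, 68). With each array centred, the splits were 104 and 88, 384 and 508 under DMF179.2, and 384 and 908 under the combination. Renewed quantile normalization gave 243 and 317 under MEF79.2. The MEF79.2 count was 44 with the groups compared alone, 127 with the control covariate, 190 with averaged probe sets and 331 without the filter. Array weights gave 473 under DMF100, 1269 under DMF179.2 and 2440 under the combination. Without DMF179.2 replicate 23, the array of lowest correlation, 352 genes were called under DMF179.2, and the calls of Elovl6, Gclm and Osgin1 ended.

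Spleen (8, 8, 8, 7, 8 and 8 arrays) showed its largest increases in genes of red cell precursors under DMF179.2. Kel, a red cell surface antigen, rose by 2.67 ± 0.90 (adjusted p = 0.028), the transferrin receptor Tfr2 by 2.41 ± 0.61, the membrane skeleton gene Ank1 by 2.29 ± 0.58 and the erythroid transcription factor Klf1 by 2.28 ± 0.66. Of the 2 other probe sets of Ank1, 1 moved the same way. Erythroid markers rose at 10 of 16 (14 adjusted over the list alone), with a mean of 1.42 ± 0.51 and a fry adjusted p of 0.0959, so the list did not pass its own test. Cell cycle genes rose at 18 of 29 (23 adjusted over the list alone), with a mean of 0.67 ± 0.24 and a fry adjusted p of 0.0956. The erythroid mean averaged 10.46 ± 0.42 (SD) in 8 DMF179.2 arrays and 9.04 ± 1.14 in 8 vehicle arrays (exact permutation p = 0.00482), and 3 of the 8 exceeded the highest vehicle array.

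**Figure D2:**
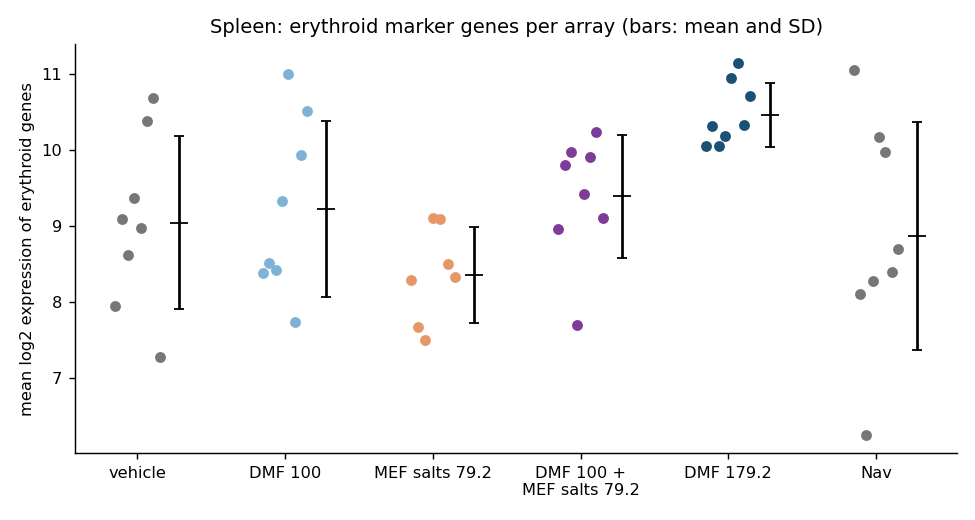
Mean log2 expression of erythroid markers in each spleen array by group, with group means and standard deviations. DMF179.2 arrays average 10.46 and vehicle arrays 9.04, and the lowest DMF179.2 array lies at 10.04.

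Nqo1 rose in spleen under DMF179.2 by 1.61 ± 0.32 (adjusted p = 0.00098), Srxn1 by 0.52 ± 0.11 and the zinc-binding Mt1 by 0.69 ± 0.17. Over 47 arrays, centred within groups, Nqo1 followed the erythroid mean (r = 0.917, permutation p = 1e-05, the smallest possible; rho = 0.911, permutation p = 1e-05; r = 0.9 without the 2 farthest arrays). Of the 4 relations computed, the NRF2 list mean gave r = 0.665 (permutation p = 1e-05; rho = 0.628, permutation p = 1e-05; 0.562 without the 2 farthest). Mt1 gave r = 0.649 (permutation p = 1e-05; rho = 0.584, permutation p = 2e-05; 0.555 without the 2 farthest). Srxn1 gave r = 0.559 (permutation p = 9e-05; rho = 0.486, permutation p = 0.00086; 0.444 without the 2 farthest). The 3' minus 5' difference of actin and Gapdh, a measure of RNA integrity, was higher by 0.196 under DMF179.2 (exact permutation p = 0.00218, adjusted p = 0.0763 over 35 comparisons). Hmox1 fell by 0.34 ± 0.13, a call that ended without the filter, after renewed quantile normalization and with the groups compared alone. NRF2 targets rose at 15 and fell at 1 of 30 (16 and 1 adjusted over the list alone; fry adjusted p = 2.33e-05, and 0.478 with an estimated correlation). DMF100 raised the heat shock partner Dnaja1 by 0.64 ± 0.09 and heat shock genes at 5 of 12 (7 adjusted over the list alone; fry adjusted p = 0.00482, and 0.381 with an estimated correlation). It lowered the interferon-responsive genes Slfn4 by 1.52 ± 0.34 and Ifit3 by 0.60 ± 0.15, the call of Ifit3 ending without the filter. The combination raised Gstm1 by 0.64 ± 0.10 and Aox1 by 0.83 ± 0.17 and lowered Vwa1 by 0.50 ± 0.10, calls that ended with the groups compared alone. Calls numbered 88 under DMF100 (53 rose, 35 fell, 7 at least 1.5-fold), 2573 under DMF179.2 (1778, 795, 354) and 3 under the combination, and with array weights 816, 4528 and 170. For MEF79.2 limma called 0 genes, with 562 at an unadjusted p under 0.05. With each array centred, the DMF179.2 split was 1065 that rose and 1743 that fell.

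The inguinal lymph node (8, 8, 6, 6, 8 and 8 arrays) showed Nqo1 up by 0.95 ± 0.11 under DMF100, 1.35 ± 0.12 under DMF179.2 (adjusted p = 1.5e-10) and 1.08 ± 0.11 under the combination, and at 0.29 ± 0.12 under MEF79.2 (adjusted p = 0.33). Fcer1a, the IgE receptor chain of mast cells and basophils, rose by 1.23 ± 0.34, 1.78 ± 0.36 and 1.64 ± 0.34, and Tnfaip2 by 0.79 ± 0.12, 0.85 ± 0.13 and 0.67 ± 0.12 under the same treatments. Fcer1a starts from a vehicle level of 3.92, below the filter's 5.44. NRF2 targets rose at 5, 7 and 2 of 30 (10, 14 and 13 adjusted over the list alone), with fry adjusted p of 0.000457, 1.64e-05 and 2e-05, and the DMF100 value was adjusted p = 0.0881 with an estimated correlation. DMF100 raised heat shock genes at 3 of 12 (8 adjusted over the list alone; fry adjusted p = 8.82e-05, and 0.0381 with an estimated correlation) and lowered Klf11 by 0.94 ± 0.17. MEF79.2 raised the transcription factor Sox9 by 0.70 ± 0.13, its 1 call, which ended with centring and with the groups compared alone, and 1 of 2 other probe sets moved the same way. Calls numbered 178 under DMF100 (109 rose, 69 fell, 12 at least 1.5-fold), 40 under DMF179.2 (39, 1, 12) and 5 under the combination. With centring the DMF100 split was 90 and 100 and the DMF179.2 split 27 and 4. Without combination replicate 35, the array of lowest correlation, 3 genes were called under the combination and Fcer1a and Slc40a1 were no longer among them. Hybridisation controls were lower by −0.17 under DMF179.2, −0.15 under the combination and −0.11 under DMF100, and with their signal as a covariate the 3 calls of Fcer1a ended, at 1.20 ± 0.37, 1.72 ± 0.43 and 1.59 ± 0.40 for DMF100, DMF179.2 and the combination. Under the combination the calls of Tnfaip2 and Slc40a1 ended too, at 0.663 ± 0.137 and 0.994 ± 0.205 (limma adjusted p = 0.0537 for each). The covariate took the MEF79.2 count from 1 to 163, and array weights took the DMF100 count from 178 to 496 and the DMF179.2 count from 40 to 565.

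In brain (8, 7, 8, 7, 8 and 8 arrays), immediate early genes, which neuronal activity induces within minutes, were higher under DMF100 than in vehicle. Tissue was taken 12 h after the last dose, and what induced these genes was not tested. Arc rose by 1.56 ± 0.24 (adjusted p = 0.00018), Nr4a1 by 1.39 ± 0.20, Egr2 by 1.17 ± 0.25 and Fos by 1.11 ± 0.23. Immediate early genes rose at 4 of 11 (7 adjusted over the list alone; fry adjusted p = 0.00922, and 0.0909 with an estimated correlation). The combination, which holds the same dose of DMF, was lower than DMF100 at Arc by −1.15 ± 0.24 and at Nr4a1 by −1.17 ± 0.20. Under DMF179.2, Arc and Nr4a1 rose by 0.97 ± 0.23 and 0.95 ± 0.19, Gstm2 by 1.14 ± 0.18, the aldehyde oxidase Aox1 by 0.85 ± 0.09 and Nqo1 by 0.90 ± 0.09. Nqo1 rose by 0.47 ± 0.10 under DMF100 and 0.62 ± 0.09 under the combination. MEF79.2 raised the clock gene Per1 by 0.79 ± 0.12 and lowered Foxq1 by 0.40 ± 0.08. NRF2 targets rose at 3, 9 and 3 of 29 under DMF100, DMF179.2 and the combination (5, 17 and 10 adjusted over the list alone), with fry adjusted p of 0.000891, 3.21e-10 and 1.59e-05, and passed with an estimated correlation. When the groups were compared alone the calls of Egr2 under DMF100 and of Arc under DMF179.2 ended.

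Calls in brain numbered 43 under DMF100 (40 rose, 3 fell, 10 at least 1.5-fold), 117 under DMF179.2 (109, 8, 11), 39 under MEF79.2 (33, 6, 1) and 32 under the combination (22, 10, 1). Centring gave 35 that rose and 70 that fell under MEF79.2, and 11 and 14 under the combination. Per1 and Foxq1 kept their calls, but without MEF79.2 replicate 25, the array of lowest correlation, MEF79.2 had 3 calls and the combination 86. Hybridisation controls were lower by −0.09 under DMF100, −0.08 under DMF179.2 and −0.10 under the combination, and with their signal as a covariate the counts under DMF179.2, MEF79.2 and the combination were 72, 179 and 2. With array weights the 4 counts were 122, 430, 282 and 717.

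In blood (7, 7, 8, 5, 6 and 5 arrays), DMF100 raised the heat shock gene Hspa1b by 2.66 ± 0.47 (adjusted p = 0.0062) and its partner Dnaja1 by 0.95 ± 0.15. Heat shock genes rose at 2 of 11 (8 adjusted over the list alone; fry adjusted p = 0.000419, and 0.0202 with an estimated correlation). The basophil and mast cell genes Fcer1a and Ms4a2 rose by 1.39 ± 0.29 and 1.13 ± 0.26 under DMF100 and by 1.33 ± 0.28 and 1.03 ± 0.25 under DMF179.2. DMF179.2 raised Lpl by 1.51 ± 0.34, Nqo1 by 0.84 ± 0.20 and thioredoxin reductase Txnrd1 by 0.42 ± 0.08, and lowered the interferon-responsive genes Slfn4 by 1.36 ± 0.29, Oasl2 by 1.04 ± 0.26 and Rtp4 by 0.87 ± 0.20. Interferon-stimulated genes fell at 2 of 21 (10 adjusted over the list alone; fry adjusted p = 0.0376, and 0.309 with an estimated correlation). NRF2 targets rose at 4 of 27 (7 adjusted over the list alone; fry adjusted p = 0.00617, and 0.309 with an estimated correlation). With the groups compared alone the calls of Fcer1a and Ms4a2 at both doses and of Lpl and Nqo1 ended, without the filter that of Oasl2 ended, and with averaged probe sets that of Rtp4.

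Calls in blood numbered 27 under DMF100 (13 rose, 14 fell, 12 at least 1.5-fold) and 139 under DMF179.2 (92, 47, 42), the latter 100 and 89 with centring. For MEF79.2 and the combination limma called 0 genes, with 1149 and 775 at an unadjusted p under 0.05. Nqo1 stood at −0.07 ± 0.23 under MEF79.2 and at 0.94 ± 0.21 under the combination (adjusted p = 0.17). Nav replicate 40, the array of lowest correlation, enters the shared variance estimate. Without it, counts were 62, 292, 16 and 3 for DMF100, DMF179.2, MEF79.2 and the combination. Leaving out vehicle replicate 3, 5 or 6 or MEF79.2 replicate 25 gave 1, 5, 16 and 6 calls for MEF79.2. Array weights gave 63, 219, 92 and 5 for the 4 treatments.

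**Figure D3:**
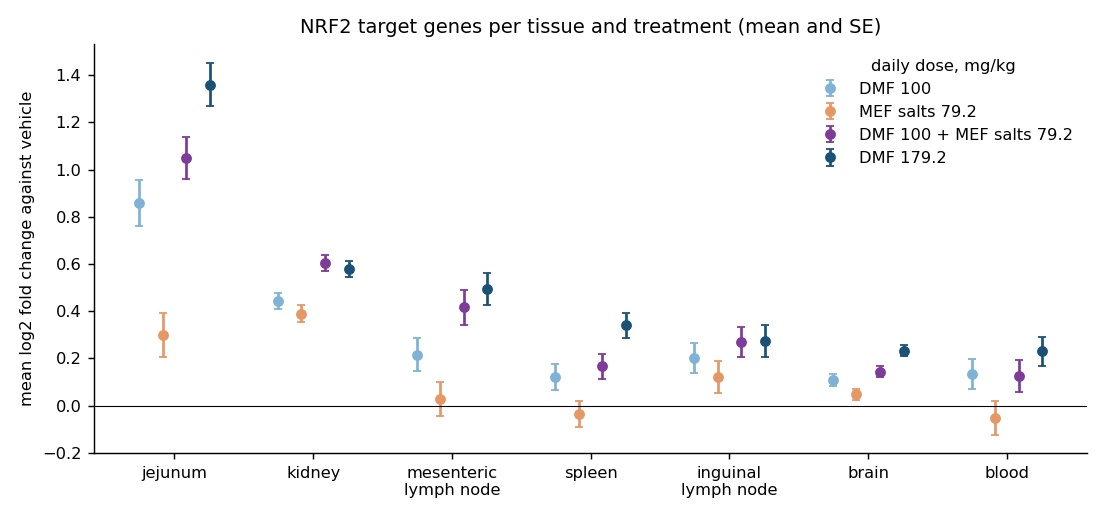
Mean log2 fold change of NRF2 target genes against vehicle by tissue and treatment, with standard errors, each tissue on its own normalization. The mean runs from −0.05 under MEF79.2 in blood to 1.36 under DMF179.2 in jejunum.

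MEF79.2 was set against DMF100 to ask where the compounds differ, at doses that are unequal in mass. In jejunum, Cbr3 was lower under MEF79.2 by −3.19 ± 0.30 (95% interval −3.80 to −2.57), Ces1g by −2.53 ± 0.45, Akr1b8 by −1.84 ± 0.23, Gstm1 by −1.51 ± 0.26 and Nqo1 by −0.79 ± 0.12. In kidney, Cbr3 differed by 0.02 ± 0.13 (interval −0.25 to 0.28) and Nqo1 by 0.07 ± 0.08 (interval −0.10 to 0.24). Aldh3a1 and Slc10a2 were lower under MEF79.2, by −1.39 ± 0.39 and −0.69 ± 0.18, and Gclm and the heme synthesis gene Alas1 were higher by 0.22 ± 0.06 and 0.45 ± 0.13. In the inguinal node Cpa3 was lower by −1.17 ± 0.22, Cma1 by −1.01 ± 0.20, Mcpt4 by −0.95 ± 0.23 and Fcer1a by −1.73 ± 0.36, with both means of Fcer1a (3.42 and 5.15) below the filter's level. In the mesenteric node Hspa1b was lower by −1.45 ± 0.26 and Angptl8 by −1.47 ± 0.35. The NRF2 list mean differed by −0.56 (interval −0.76 to −0.36) in jejunum, −0.19 (−0.33 to −0.04) in the mesenteric node, −0.16 (−0.27 to −0.05) in spleen, −0.19 (−0.33 to −0.04) in blood and −0.06 (−0.11 to −0.01) in brain. Its intervals included 0 in kidney, −0.06 (−0.12 to 0.01), and the inguinal node, −0.08 (−0.22 to 0.06). In spleen the list mean followed the erythroid mean within groups (r = 0.665), and the erythroid mean was 8.35 under MEF79.2 and 9.23 under DMF100. That spleen difference cannot be separated from the one in erythroid genes. Calls numbered 1437 in the mesenteric node, 380 in brain, 257 in kidney, 55 in the inguinal node, 15 in jejunum and 10 in spleen, in all 2154. For blood limma called 0, with 975 at an unadjusted p under 0.05. The total was 3754 with array weights and 1249 with the control covariate. Centring moved the split from 285 higher and 95 lower to 240 and 170 in brain, from 164 and 93 to 128 and 146 in kidney, from 329 and 1108 to 473 and 718 in the mesenteric node and from 7 and 48 to 14 and 31 in the inguinal node.

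DMF179.2 and the combination carry the same total mass, 179.2 mg/kg, and were set against each other at that equal mass. In spleen, the erythroid gene Ank1 was higher under DMF179.2 by 1.89 ± 0.58 and Plek2 by 1.51 ± 0.45, and the protease Ctso was lower by −0.58 ± 0.14. In kidney, Klk1b16 was higher by 0.76 ± 0.13 and the regulator Id1 lower by −0.54 ± 0.11, and Gclm was lower by −0.20 ± 0.06. For jejunum limma called 0 genes, with 1252 at an unadjusted p under 0.05, and Cbr3 was at 1.02 ± 0.28 (interval 0.44 to 1.59, adjusted p = 0.257). The NRF2 list mean was higher under DMF179.2 in jejunum by 0.31 (interval 0.12 to 0.50), in spleen by 0.17 (0.06 to 0.28) and in brain by 0.09 (0.04 to 0.14). Its intervals included 0 in kidney, −0.03 (−0.09 to 0.04), the inguinal node, 0.00 (−0.13 to 0.14), the mesenteric node, 0.08 (−0.07 to 0.23), and blood, 0.10 (−0.03 to 0.24). In spleen the list mean followed the erythroid mean within groups (r = 0.665), and the erythroid mean was 10.46 under DMF179.2 and 9.39 under the combination. The spleen difference therefore cannot be separated from that in erythroid genes. Calls numbered 1222 in kidney, 595 in spleen, and 1 each in brain, Nfatc3, and the mesenteric node, Frat1, in all 1819. For blood and the inguinal node limma called 0, with 685 and 555 at an unadjusted p under 0.05. Centring moved the spleen split from 433 higher and 162 lower to 257 and 819.

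The higher DMF dose was set against the lower to ask for a dose response. In jejunum, the epoxide hydrolase Ephx1 was higher by 1.92 ± 0.33 and Cbr3 by 1.73 ± 0.30, whereas Lgr5, a marker of crypt stem cells, was lower by −1.35 ± 0.31. Nqo1 was higher by 0.76 ± 0.13 in the mesenteric node, where Hspa1b was lower by −0.99 ± 0.25. In kidney the injury marker Lcn2 was higher by 1.47 ± 0.37 and Slc10a2 lower by −0.87 ± 0.17, and in spleen the mitotic gene Cdca5 was higher by 1.12 ± 0.27. Calls numbered 1263 in jejunum (745 higher, 518 lower), 270 in spleen, 146 in kidney, 63 in the mesenteric node, 2 in brain, Ecm1 and Unc5d, and 1 in the inguinal node, Prorp, in all 1745. For blood limma called 0, with 1158 at an unadjusted p under 0.05. Array weights took the total to 5609. Centring moved the split from 186 higher and 84 lower to 211 and 450 in spleen and from 116 and 30 to 79 and 59 in kidney.

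The combination was set against DMF100 to ask what MEF salts add. In kidney, Lcn2 was higher by 1.14 ± 0.37, and Slc10a2 and the cold-inducible Rbm3 were lower by −0.92 ± 0.17 and −0.99 ± 0.13. In the mesenteric node, Alox15 was higher by 1.56 ± 0.38 and Hspa1b lower by −1.36 ± 0.27. In jejunum, the stress gene Atf3 was lower by −1.63 ± 0.27 and the tight junction gene Cldn4 by −1.24 ± 0.20. The inguinal node showed Klf11 higher by 0.87 ± 0.17 and Dnaja1 lower by −0.38 ± 0.07. Calls numbered 1566 in kidney, 940 in the mesenteric node, 19 in the inguinal node, 17 in jejunum and 10 in brain, in all 2552. For spleen and blood limma called 0, with 739 and 589 at an unadjusted p under 0.05. With the control covariate the total was 1482. Centring moved the split from 951 higher and 615 lower to 687 and 895 in kidney and from 469 and 471 to 305 and 786 in the mesenteric node.

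Departure from the sum of DMF100 and MEF79.2 on the log2 scale was called as positive 145 times and as negative 150 times. The split was 51 and 30 in the inguinal node, 65 and 61 in kidney and 18 and 17 in the mesenteric node. It was 8 and 24 in jejunum and 2 and 17 in brain. With each array centred it was 41 and 38 in the inguinal node and 58 and 90 in kidney. Cbr3 in kidney, which both compounds raised, departed by −1.80 ± 0.19 (adjusted p = 2.6e-08). Cyp2d9 in kidney departed by −1.53 ± 0.33, and Ces1f in jejunum by −1.56 ± 0.36. Atf3 and Fosb in jejunum departed by −2.15 ± 0.37 and −2.19 ± 0.49, and Arc, Nr4a1 and Egr2 in brain by −1.90 ± 0.34, −1.87 ± 0.28 and −1.77 ± 0.35. Klf11 departed upward, by 1.47 ± 0.32 in kidney and 1.20 ± 0.24 in the inguinal node. Calls numbered 126 in kidney, 81 in the inguinal node, 35 in the mesenteric node, 32 in jejunum, 19 in brain and 2 in blood, Ttc38 and Tpst2, in all 295. For spleen limma called 0, with 720 at an unadjusted p under 0.05. The total was 185 without the filter, 461 with the control covariate and 1598 with array weights.

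**Figure D4:**
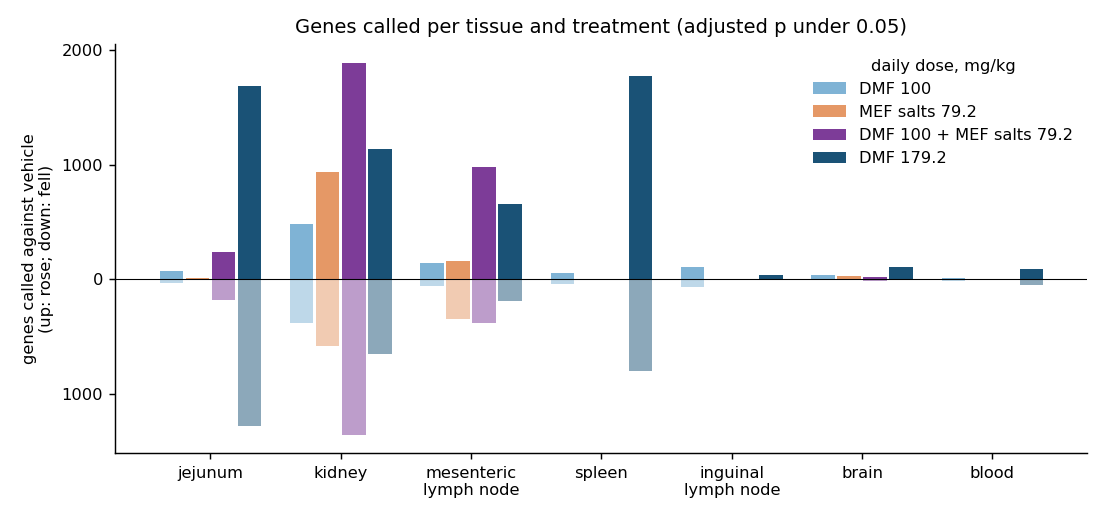
Number of genes called against vehicle by tissue and treatment. DMF179.2 has 2969 calls in jejunum and 2573 in spleen, and MEF79.2 has 0 in spleen.

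Whether responses differ among tissues was tested on 7849 genes. Glutathione transferase Gstm1 had the highest F for DMF179.2 (61.8, adjusted p = 3.11e-27), DMF100 (32.8, adjusted p = 2.09e-17) and the combination (40.6, adjusted p = 1.92e-20). For MEF79.2 it was Alas1, the first enzyme of heme synthesis (24.4, adjusted p = 4.05e-13), followed by Gstp1 (20.3). The carbonyl reductase Cbr1 and Ephx1 were among the first 5 for DMF179.2, with F of 28.1 and 27. Responses differed at 290 genes for DMF100, 2667 for DMF179.2, 972 for MEF79.2 and 1047 for the combination. Without the filter they differed at 986, 4767, 1791 and 2249, and with the stricter filter at 168 for DMF100 and 1759 for DMF179.2. With the replicate number as a block they differed at 522, 3436, 1607 and 2361.

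Fold changes of DMF100 and MEF79.2 were correlated across genes, which are not independent replicates, in kidney (r = 0.65) and jejunum (r = 0.692). Sharing the vehicle arrays alone gave 0.512 and 0.446 in simulations, and vehicle arrays split between the treatments gave 0.419 and 0.438. The covariance was 0.0158 in kidney and 0.0264 in jejunum, against 0.00393 and 0.00879 simulated. In the mesenteric node (0.00498), brain (0.00189) and spleen (0.00773) it was below the simulated 0.00778, 0.00253 and 0.00954. It was 0.017 in blood against 0.0106, and 0.00631 in the inguinal node against 0.00608. DMF179.2 and the combination gave r = 0.854 in jejunum, against 0.482 simulated and 0.734 with split vehicle arrays. In spleen r was 0.428, below the simulated 0.503, and 0.181 with split vehicle arrays. The spleen covariance of this pair, 0.0146, was nevertheless above the simulated 0.00953. The r was 0.748 in the mesenteric node, 0.734 in kidney, 0.624 in blood, 0.597 in brain and 0.563 in the inguinal node, against 0.454, 0.53, 0.496, 0.501 and 0.463 simulated.

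The group labelled Nav was also set against vehicle, a comparison whose purpose the labels do not state. In kidney, the secretory granule gene Sycn was higher by 2.00 ± 0.59, the clock output gene Dbp by 1.41 ± 0.30 and Per1 by 0.97 ± 0.31, and Cyp4a31 was lower by −1.28 ± 0.15. In the mesenteric node, S100a9, a neutrophil gene, was higher by 1.39 ± 0.48, the adipocyte gene Lep by 1.20 ± 0.47 and Sncg by 1.36 ± 0.28, and Klra9 was lower by −1.68 ± 0.27. Sycn had an SD of 2.75 in Nav and 0.24 in vehicle, and S100a9 one of 1.79 and 0.59. In brain, Hcrt, the precursor of the wakefulness peptide orexin, was lower by −1.93 ± 0.51, with an SD of 2.24 in Nav and 0.4 in vehicle, and in jejunum Per3 was higher by 1.16 ± 0.32. Calls numbered 5401 in the mesenteric node (519 at least 1.5-fold), 5332 in kidney (163), 1411 in spleen (46), 854 in jejunum (84), 412 in brain (6), 2 in the inguinal node, Zmat3 and Rai14 (the latter with 0 of 2 other probe sets in the same direction), and 2 in blood, Man1c1 and Ndufaf8, in all 13414. Centring moved the split from 550 higher and 304 lower to 312 and 561 in jejunum and from 3178 and 2223 to 2480 and 2666 in the mesenteric node. Renewed quantile normalization moved spleen from 851 and 560 to 1299 and 520. Hybridisation controls were higher in Nav by 0.24 in kidney and 0.22 in the mesenteric node, and lower by −0.14 in jejunum and −0.14 in the inguinal node. With their signal as a covariate Nav had 8650 calls, with 3143 in kidney, 3186 in the mesenteric node, 1759 in spleen, 454 in brain, 107 in the inguinal node, 1 in blood and, in limma, 0 in jejunum.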

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

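The test of blood left in the spleen and the counts over random splits were chosen only after the results were seen.

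In kidney and the mesenteric node, 5332 and 5401 genes differed between Nav and vehicle, mostly by small folds. RNA integrity is argued against, since the 3' minus 5' difference of actin and Gapdh moved by 0.021 and −0.044. A labelling or hybridisation run may contribute, since added control transcripts were higher in Nav by 0.235 and 0.216 (exact permutation test), but 3143 and 3186 genes were called with their signal as a covariate, 2910 and 3041 of them the same genes. Time of day stays open, since only 1 clock gene, Per3, was called with 1 sign in at least 5 of 7 tissues. In kidney 10 of 15 clock genes were called, with Per1, Per3, Dbp, Tef, Hlf and Ciart higher and Arntl, Npas2, Clock and Cry1 lower. In the mesenteric node 7 of 15 were called (5 higher, 2 lower), each with its sign in kidney. Blood and the inguinal node had 0 clock calls and brain and spleen 1 each, so no other gene could meet the rule of 5 tissues. What separates Nav from vehicle by design is untested.

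Erythroid genes were higher in spleen under DMF179.2, with a list mean of 1.42 ± 0.508. A smaller share of lymphocyte RNA is argued against, since monocyte and macrophage markers stood at 0.003 ± 0.105 where such a loss would raise every other cell type. Blood left in the organ stays open although several values speak against it as the whole cause, since neutrophil markers stood at 0.014 ± 0.334, platelet markers at 0.137 ± 0.141 and Hba-a1 at 0.10, and Rhag, the 1 member dim in blood, rose by 2.10 against a median of 1.44 for the other 15, but spleen holds these cells itself and 1 gene decides little. Only 3 of 8 DMF179.2 arrays lay above the highest vehicle array, as a change carried by a few animals predicted. That count depends on the wide vehicle range, 7.27 to 10.69, and so cannot decide the question. All 8 DMF179.2 arrays lay between 10.04 and 11.15, above the vehicle mean of 9.04. This argues against a change carried by a few of the treated animals. A treatment effect on red cell formation remains a hypothesis, and RNA integrity is not excluded, since the 3' minus 5' difference was higher by 0.196 (exact permutation p = 0.00218).

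Fabp6 and Fgf15 fell in jejunum under DMF179.2, and Onecut2, a gene of the upper small intestine chosen after its value was seen, rose by 2.98. A piece taken nearer the stomach stays open, since distal minus proximal markers gave a median difference of −0.28, with Pyy down by −1.15, Treh up by 0.70 and Slc10a2, whose fall this explanation needs, at −2.00 ± 0.88 (limma adjusted p = 0.0831). Lower activity of the bile acid receptor FXR stays open, since 1 of 3 further targets fell, Slc51a by −0.59, while Nr0b2 rose by 1.55 and Slc10a2, which should not fall under it, is undecided. Position that varies between animals is consistent with the correlation of Fabp6 and Onecut2 over 15 vehicle and Nav arrays (r = −0.891, permutation p = 1e-05, the smallest possible; rho = −0.907, permutation p = 2e-05; −0.861 without the 2 farthest arrays; −0.864 in vehicle and −0.915 in Nav). A treatment effect on bile acid genes is not excluded.

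An array apart from its group was found in 15 of 126 tests, each of 1 group and 1 of 3 measures, where chance gives about 1 in 20 (5%). Values are the gap to the nearest array over the group's range. In the NRF2 list mean, blood MEF79.2 replicate 27 was highest with 0.741, inguinal node Nav replicate 40 with 0.558 and inguinal node vehicle replicate 2 with 0.546. In Nqo1, jejunum MEF79.2 replicate 29 was lowest with 0.687 and mesenteric node Nav replicate 40 highest with 0.569. In median correlation with the arrays of its tissue, the lowest arrays were Nav replicate 40 in blood (0.853), mesenteric node (0.599) and spleen (0.533), DMF179.2 replicate 24 (0.593) and MEF79.2 replicate 25 (0.599) in brain, MEF79.2 replicate 27 (0.649) and vehicle replicate 6 (0.629) in the inguinal node, DMF100 replicate 12 in kidney (0.65), and DMF179.2 replicate 23 (0.683) and MEF79.2 replicate 30 (0.632) in the mesenteric node.

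Responses that differed among the 7 tissues, by the interaction test, numbered 290 for DMF100, 2667 for DMF179.2, 972 for MEF79.2 and 1047 for the combination. Probe sets without a gene name, which no comparison used, were called under DMF179.2 at 51 in blood, 16 in brain, 5 in the inguinal node, 1918 in jejunum, 897 in kidney, 477 in the mesenteric node and 2650 in spleen. That is 39.1% of those tested in spleen, against 24.4% of named genes, and 30.2% against 27.4% in jejunum. In spleen 855 rose and 1795 fell, against 1778 and 795 of named genes. In jejunum the splits were 780 and 1138 against 1688 and 1281, and in kidney 352 and 545 against 1134 and 652. The mesenteric node gave 156 and 321 against 656 and 185. In these tissues the surplus of rises among named genes was therefore not shared. Elsewhere 24 rose and 27 fell in blood, 14 and 2 in brain, and 4 and 1 in the inguinal node. The share was lower than that of named genes in kidney (14.5% against 16.7%), the mesenteric node (7.22% against 7.88%), blood (0.756% against 1.34%), brain (0.258% against 1.09%) and the inguinal node (0.0746% against 0.379%).

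Of 100 splits of the same arrays, the real one included, 1 gave as many calls for the counts that follow, so chance is unlikely for each taken alone. This is the smallest share that 100 splits can give, and it is not adjusted over the counts tested. Other splits still called many genes, up to 1942 for the combination in kidney and 8110 for Nav. The real count and the highest of the other splits were 27 and 1 for DMF100 in blood. In brain they were 43 and 7 for DMF100 and 117 and 9 for DMF179.2. For the inguinal node they were 178 and 29 for DMF100 and 40 and 2 for DMF179.2. Jejunum gave 108 and 9, 2969 and 824, 12 and 2, and 416 and 216 for DMF100, DMF179.2, MEF79.2 and the combination. Kidney gave 866 and 295, 1786 and 332, 1520 and 43, and 3245 and 1942 in the same order. In the mesenteric node they were 197 and 69 for DMF100, 507 and 1 for MEF79.2 and 1358 and 402 for the combination, and in spleen 2573 and 63 for DMF179.2. Summed over tissues they were 13414 and 8110 for Nav, 2552 and 1736 for the combination against DMF100, 1745 and 544 for DMF179.2 against DMF100, 1819 and 1596 for DMF179.2 against the combination, and 2154 and 1011 for MEF79.2 against DMF100. For the interaction they were 290 and 162, 2667 and 1104, 972 and 312, and 1047 and 214.

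Taken alone, chance is also unlikely at 2 of 100 splits for DMF179.2 in blood (139, highest other 149) and in the mesenteric node (841, highest other 1191), and for the departure from additivity (295, highest other 2209). The same holds at 3 of 100 for MEF79.2 (39, highest other 772) and the combination (32, highest other 62) in brain, the combination in the inguinal node (5, highest other 600), and DMF100 (88, highest other 184) and the combination (3, highest other 13) in spleen, and at 4 of 100 for MEF79.2 in the inguinal node (1, highest other 612). Splits that called several times the real count, as in brain for MEF79.2, in the inguinal node and for additivity, point to a structure of the samples. Its source was not tested, although same-numbered arrays correlated more in 21 of 21 tissue pairs. Without the array of lowest correlation, brain had 3 calls for MEF79.2. These shares are not adjusted over the counts tested, so chance is not held excluded, least of all for counts of 1, 3 and 5. The inguinal node's MEF79.2 call was 0 with centring, the stricter filter or the groups compared alone. Where the real count is 0, all 100 splits match it by construction and say nothing about chance, as for MEF79.2 in blood (highest other 12), the combination in blood (highest other 51) and MEF79.2 in spleen (highest other 3).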

How the results depend on the processing

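The alternatives that left out arrays of lowest correlation or used the hybridisation controls as a covariate were chosen after seeing the data. Nqo1 and Cbr3 kept their direction and calls in jejunum and kidney under DMF100, DMF179.2 and the combination in every alternative run. Over all alternatives, 253 of 351 counts of calls stayed within 1.5 times the reported count and 98 moved, 11 of 20 interaction counts stayed and 9 moved, and 189 of 274 list tests stayed past the threshold while 85 did not. Jejunum, kidney and spleen had no array of low correlation to leave out, so their counts and named genes stayed by construction there. Leaving out a blood Nav array could hardly move the Nav total of 13414, to which blood gives 2 calls. The genes named by size and the fixed set, each against vehicle, gave 5740 values. Of these, 5342 kept their call or stayed without one, 378 lost the call and 20 gained it. None of the values called in the main fit reversed. For values not called there, direction was not compared. Genes named only as list members, in direct comparisons, for additivity or for Nav were not rerun. With camera's estimated correlation 19 of 92 list calls passed, a test against other genes rather than against no change. With vehicle arrays split, the median correlation between treatments was 0.25. Values near the lowest signal of a tissue limit what dim genes can show. For each value below the cause was not tested, except that filters change the number of genes tested and comparing the groups alone uses fewer arrays.

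With no filter, blood gave 10 for DMF100 and 1 for the combination, the inguinal node 105 for DMF100 and 3 for MEF79.2, jejunum 5 for MEF79.2, the mesenteric node 128 for DMF100 and 331 for MEF79.2, spleen 1 for the combination, and additivity 185. The interaction gave 986, 4767, 1791 and 2249. With the filter at the 70th percentile, blood gave 44 for DMF100, brain 26, 53, 18 and 52 for DMF100, DMF179.2, MEF79.2 and the combination, the inguinal node 0 for MEF79.2 and 3 for the combination, spleen 1 for the combination, and the interaction 168 for DMF100 and 1759 for DMF179.2.

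With renewed quantile normalization, blood gave 1 for the combination, brain 9 and the inguinal node 4 for MEF79.2. Centring gave 73 and 105 in brain for DMF179.2 and MEF79.2, and 0 in the inguinal node for MEF79.2. Trended robust variance gave 1 in blood for the combination, 25 in brain for MEF79.2 and 11 in the inguinal node for the combination. The mean of a gene's probe sets gave 43 and 3 in blood for DMF100 and the combination, and for MEF79.2 64 in brain, 6 in jejunum and 190 in the mesenteric node.

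Array weights gave 63, 219, 92 and 5 in blood, 122, 430, 282 and 717 in brain, 496, 565, 10 and 10 in the inguinal node, and 816, 4528, 1 and 170 in spleen, for DMF100, DMF179.2, MEF79.2 and the combination. They gave 521 for DMF100 and 197 for MEF79.2 in jejunum, 2684 for MEF79.2 in kidney, 473, 1269 and 2440 for DMF100, DMF179.2 and the combination in the mesenteric node, 5609 for DMF179.2 against DMF100, 3754 for MEF79.2 against DMF100, and 1598 for additivity.

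With the groups compared alone, blood gave 33 for DMF179.2, brain 28, 50, 6 and 11, the inguinal node 59, 0 and 9 for DMF100, MEF79.2 and the combination, jejunum 3 for MEF79.2 and 186 for the combination, the mesenteric node 58, 480 and 44 for DMF100, DMF179.2 and MEF79.2, and spleen 29 for DMF100 and 1 for the combination. Without the arrays of lowest correlation, blood gave 62, 292, 16 and 3, brain 3 for MEF79.2 and 86 for the combination, the inguinal node 3 for the combination and the mesenteric node 352 for DMF179.2. With the hybridisation controls as a covariate, jejunum gave 69, 1128, 5 and 50, brain 72, 179 and 2 and the inguinal node 25, 163 and 2 for DMF179.2, MEF79.2 and the combination, the mesenteric node 127 for MEF79.2, and summed over tissues 8650 for Nav, 1482 for the combination against DMF100, 1249 for MEF79.2 against DMF100 and 461 for additivity. Leaving out single arrays, MEF79.2 in blood ranged from 0 to 16 calls.

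With the replicate block, 522, 3436, 1607 and 2361 genes differed among tissues for DMF100, DMF179.2, MEF79.2 and the combination, 287, 2661, 971 and 1046 of them the same genes. Arrays of the same number in different tissues correlated at a median of 0.142 in their deviations, against −0.0213 for other numbers. Of 866 such same-number pairs, 61.4% were over 0.1. Same-numbered arrays correlated more in 21 of 21 tissue pairs. Of the arrays, 53.9% had their best match in another tissue at the same number, against a median chance of 12.5%. These values argue against the independence of arrays between tissues that the counts without the block assume. The labels do not state that equal numbers are the same animal.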

Other observations

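The grouping of genes in this part was chosen only after the results were seen. Klf11, a repressor in glucose and lipid regulation, fell under DMF100 in several tissues and departed upward from additivity in the combination, and Rbm3, a cold-inducible RNA-binding protein, moved the other way. Rbm3 rose under DMF100 by 0.85 ± 0.18 in brain and 0.66 ± 0.12 in the inguinal node and departed from additivity by −1.12 ± 0.25 and −0.72 ± 0.17, with −1.11 ± 0.20 in kidney and −0.80 ± 0.16 in the mesenteric node. Klf11 fell by 1.13 ± 0.22 in kidney, by 0.84 ± 0.18 in spleen and by 0.94 ± 0.17 in the inguinal node under DMF100. The calls of Rbm3 in brain and Klf11 in spleen ended with the groups compared alone.

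Heat shock genes were higher under DMF100 than in vehicle in blood, both lymph nodes and spleen. The list means were 0.70 ± 0.12 in blood, 0.25 ± 0.05 in the inguinal node, 0.44 ± 0.07 in the mesenteric node and 0.26 ± 0.07 in spleen. Each is on its tissue's own normalization. The mean in the inguinal node under MEF79.2 was 0.19 ± 0.06, with 0 members called in limma (3 adjusted over the list alone). With an estimated correlation the lists passed in blood and both nodes (adjusted p = 0.0202, 0.0381 and 0.0226), but not in spleen (adjusted p = 0.381). The other groups given DMF did not share all of this. Hspa1b in the mesenteric node was lower under DMF179.2 and under the combination than under DMF100. Dnaja1 in the inguinal node was lower under the combination than under DMF100. Same-numbered arrays correlated more in 21 of 21 tissue pairs, so the tissues may not be independent repeats. No explanation for these values was tested.

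The erythroid mean in spleen was 9.23 ± 1.16 (SD) under DMF100, 8.35 ± 0.63 under MEF79.2, 9.39 ± 0.81 under the combination and 8.86 ± 1.5 in Nav.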
